A study of Homo sapiens with 2 samples.

How the data were processed

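H3K27ac HiChIP was carried out on 2 replicate libraries of wild-type L3.6pl cells. Per the labels' protocols, cells were fixed with 1% formaldehyde, chromatin was cut with MboI, DpnII and HinfI (200 U, 2 hours, 37 °C), ends were filled with biotin-labelled nucleotides and ligated, and sonicated chromatin was precipitated with 6 µg of antibody against H3K27ac. Nothing in the labels says whether the replicates came from separate cultures. HiC-Pro and the hg19 build are named in the submitters' processing notes, with no version. The interaction caller, its threshold and the way p63 binding and acetylation were used to select interactions were not given in the sources used here.

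The deposited list has 8 columns and no header: the positions of both bins of an interaction, and 2 columns of whole numbers, both treated as count values as deposited by the authors, with no normalization seen. Both libraries point to this 1 list, so it was taken as pooled by the authors. Column 7 was read as read pairs per interaction and column 8 as coverage of the left bin. The basis was that column 8 was constant within a left bin. The summed column 7 exceeded it in 0 of 17287 left bins (equal in 103). When the column 8 values were shuffled among left bins, 100 times, it was exceeded in 365 to 442 left bins. Totals of the list count listed pairs and are not the depth of a library.

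Distances were taken between bin starts, which equals centre to centre. Partners were counted per bin, hubs were bins with at least 5 partners, and networks were bins joined through interactions. Shares have 95% exact Clopper-Pearson intervals, which cover counting error only. Medians and correlations have percentile intervals from resampled 5 Mb blocks (2000 resamples, 500 for correlations), and these describe variation along the genome, not between replicates. Interactions per chromosome were compared with the span between the first and last listed bin by a chi-square test with 100000 multinomial draws. The alternative expectation used the number of protein-coding genes per chromosome from a GRCh38.p14 gene table, from which no coordinate was used. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

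The rule for named items, the tests and most alternatives were fixed before the data were examined. The rule named genes by their number of partners only if an annotation of the list's build was at hand, and otherwise the 10 bins with most partners and the 5 longest interactions. The second case applied. Windows, stretches, networks, the most covered bins and the interactions with most read pairs were named by rank, which was chosen after the data were seen. For lack of an hg19 annotation here, 3 planned results were not run: promoter and distal classes, enrichment of 18 fixed gene lists, and assignment of enhancers to target genes. The planned stricter selection by score used left-bin coverage, since most read-pair values are tied at 1.

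Further tests were chosen after the data were seen. Steps of left-bin coverage were sought on 19 chromosomes with at least 400 left bins, by the best split with at least 100 left bins on each side against 1000 reorderings of 1 Mb pieces. The sides of partners were tested for 193 bins by binomial tests, with equal sides or the layout of listed bins as expectation, the latter also without the bins listed through the tested bin alone. Interactions of 5 or more read pairs were compared with those of 4 in 5 exact tests. Neighbouring interactions were compared with 100 lists in which right bins were swapped within chromosome and distance class. The tests of steps, of sides and of interactions with many read pairs were each adjusted as a family by the Benjamini-Hochberg method. The neighbour comparisons gave no p-value and were not adjusted.

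The procedures were tested on simulated data. The chromosome intervals held the true ratio on 23 of 23 chromosomes. Interactions were placed independently and evenly along each chromosome there, so the intervals were not tested under the clustering of the real list. Of 5 planted coverage steps 5 were found, with 0 calls on other chromosomes among the 19 simulated. That simulation shuffled coverage along chromosomes and so did not contain the local runs of the real list. Of 16 bins planted with 14 partners on 1 side, 13 were found and 1 other bin was called. The planted partners were drawn from bins already in the list. That simulation therefore did not reproduce bins whose own partners make up much of the layout. The number found does not give the power of the test on the real list.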

Results

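Contacts between active regulatory regions were measured by H3K27ac HiChIP in L3.6pl, an established pancreatic adenocarcinoma cell line. HiChIP joins DNA ends that lie close together in the fixed nucleus and then enriches the joined fragments with an antibody, here against H3K27ac, a histone mark of active promoters and enhancers. The design text gives the purpose as finding interactions between active enhancers and promoters that are bound by p63, a transcription factor of basal epithelial cells. The series held 1 group of wild-type cells with 2 replicate libraries, and both libraries were represented by 1 pooled list of interactions. No comparison between groups and no spread between replicates could therefore be given. The list held 25546 interactions between bins of 2 kb in hg19 coordinates, carrying 26745 read pairs in all. The sequencing depth of each library was not given in the sources used here. Regions are named by position, since no gene annotation of this build was used here.

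The densest 1 Mb of the list lay on chromosome 8 from 128000001 to 129000000, where 268 interactions began. They left from 95 different bins, spanned a median of 139 kb, and 37 bins of this window had 5 or more partners. The next window was on chromosome 22 from 46000001 to 47000000, with 228 interactions, a median distance of 65 kb and 24 bins with 5 or more partners. On chromosome 17, 174 interactions began between 73000001 and 74000000, and 141 between 38000001 and 39000000. Chromosome 11 had 3 windows among the first 10, with 166 interactions from 64000001 to 65000000, 164 from 69000001 to 70000000, and 151 from 65000001 to 66000000. The other windows among the first 10 were on chromosome 7 from 1 to 1000000 (155 interactions), chromosome 19 from 45000001 to 46000000 (131) and chromosome 8 from 29000001 to 30000000 (128). These 10 windows held 6.68% of all interactions. The median over the 1769 windows with any interaction was 6. Median left-bin coverage was 22 in the window at 128000001 on chromosome 8 and in that at 69000001 on chromosome 11, and 14 to 17 in the other 8, against 12 over all left bins.

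**Figure D1:**
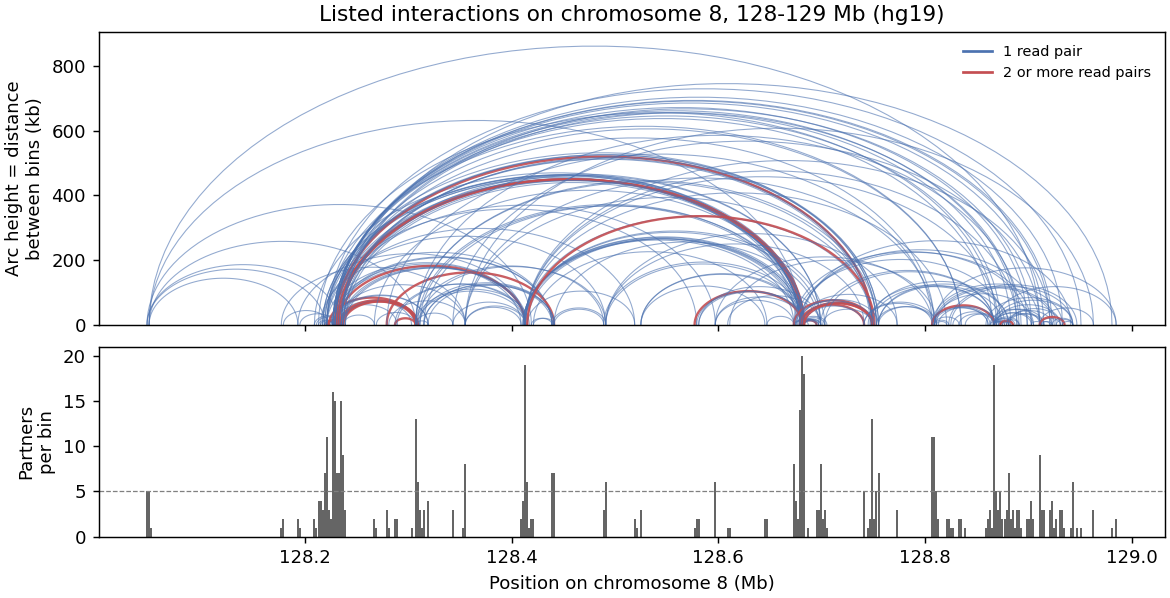
Interactions with both bins inside the densest window, chromosome 8 from 128000001 to 129000000 in hg19 (position in Mb on the horizontal axis). Each arc in the upper panel is 1 of 245 interactions, its height is the distance between the bins in kb, and the 22 with 2 or more read pairs are red; bars in the lower panel give the number of partners per bin, with a dashed line at 5.

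Single bins with many partners lay largely in the same places. The bin on chromosome 22 from 46466001 to 46468000 and the bin on chromosome 7 from 100464001 to 100466000 each had 23 partners, the most in the list. Partners of the first lay at a median of 38 kb and at most 200 kb away. Those of the second lay at a median of 174 kb and at most 1464 kb away. On chromosome 22, the bins starting at 46410001 and 46402001 had 22 and 20 partners. On chromosome 8, the bin starting at 128680001 had 20 partners at a median of 268 kb, and those starting at 128412001 and 128866001 had 19 each, at medians of 220 kb and 48 kb. The remaining bins among the first 10 were on chromosome 11, starting at 62368001 (21 partners) and 64038001 (19), and on chromosome 12, starting at 52540001 (21). Of the 21 partners on chromosome 12, 20 lay at higher positions. The binomial test of this bin gave an adjusted p of 0.00202 against equal sides. Against the layout of listed bins, which put 23.4% of partners at lower positions, it gave 0.548.

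Bins with 5 or more partners, called hubs here, made up 1479 of the 28697 different bins, or 5.15% (95% exact Clopper-Pearson interval 4.90 to 5.42). They took part in 9330 interactions, 36.5% of the list. A single partner was listed for 18093 bins, and 193 bins had at least 10. Joining bins through their interactions gave 5431 networks, of which 3055 were a single interaction and 29 had 100 or more bins. The largest network ran on chromosome 11 from 57044001 to 78078000, with 791 bins and 1055 interactions. The next was on chromosome 17 from 34888001 to 49342000, with 636 bins, followed by chromosome 22 from 35746001 to 51174000, with 508 bins. With interactions of 1 read pair left out, 2 bins had 5 or more partners. With touching bins merged, 2076 of 18088 regions did, or 11.5%.

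Touching bins formed 18088 stretches, and 373 of these were 10 kb or longer. The longest stretch covered 74 kb on chromosome 2 from 28572001 to 28646000, with 37 bins and contacts to 26 other stretches. It was followed by 56 kb on chromosome 22 from 46458001 to 46514000 (22 partner stretches), 46 kb on chromosome 17 from 38666001 to 38712000 (19) and 40 kb on chromosome 8 from 29580001 to 29620000 (22).

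All listed interactions joined bins of the same chromosome, over a median distance of 90 kb (95% interval 86 to 94 from resampled 5 Mb blocks). The quartiles were 30 and 298 kb. Distances under 100 kb made up 52.1% (51.5 to 52.7), those from 100 kb to under 1 Mb 39.4% (38.8 to 40.0), and those of 1 Mb or more 8.51% (8.17 to 8.86). The shortest distance was 10 kb and the longest 4998 kb, on chromosome 20 from the bin starting at 5638001 to the bin starting at 10636001. The next longest were 4994 kb on chromosome 17 (43508001 and 48502001), 4992 kb on chromosome 2 (4948001 and 9940001), 4990 kb on chromosome 2 (203674001 and 208664001) and 4980 kb on chromosome 19 (490001 and 5470001). Each of these 5 rested on 1 read pair. The median, shares and ranks hold within the listed range of 10 to 4998 kb on the same chromosome. The sources used here do not say whether the list was cut at these limits. The intervals of shares cover counting error only.

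**Figure D2:**
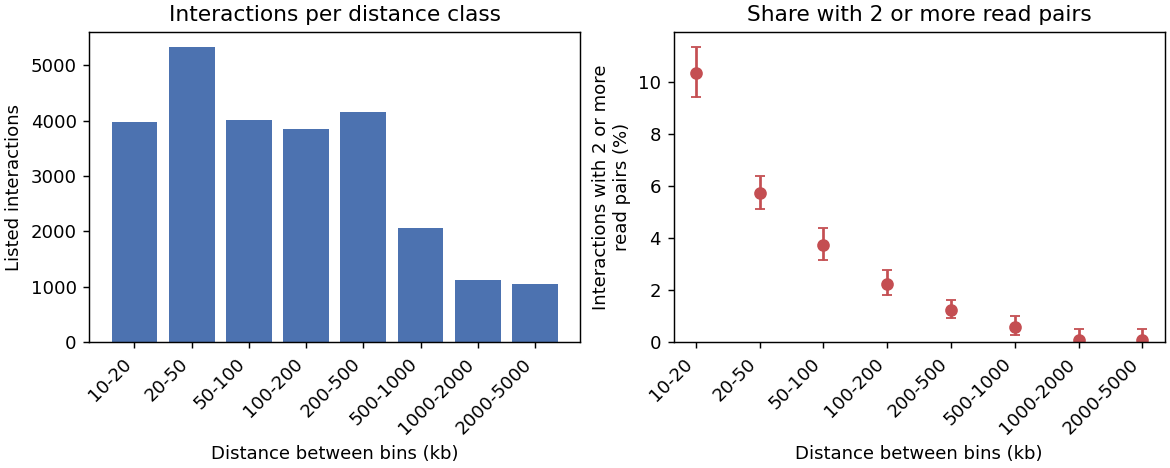
Left, the number of listed interactions in each class of distance between bins (kb). Right, the percent of interactions in each class with 2 or more read pairs, with 95% exact binomial intervals, which fell from 10.4% at 10 to 20 kb to 0.0951% at 2000 to 5000 kb.

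Nearly all interactions, 24525 or 96.0% (95.8 to 96.2), carried 1 read pair. The 1021 with 2 or more made up 4.00% (3.76 to 4.24). This share was 10.4% (9.44 to 11.4) at 10 to 20 kb, 3.75% (3.18 to 4.38) at 50 to 100 kb, 2.26% (1.82 to 2.78) at 100 to 200 kb and 0.0890% (0.00225 to 0.495) at 1000 to 2000 kb. Across interactions, which are not independent replicates, Spearman's rho of read pairs with distance was -0.16 (95% block interval -0.18 to -0.15). Keeping only interactions of 2 or more read pairs lowered the median distance from 90 to 24 kb. The most read pairs, 27, joined bins of chromosome X starting at 57618001 and 57936001, 318 kb apart. The next were 16 on chromosome 1 (155532001 and 155658001, 126 kb) and 11 on chromosome 15 (45122001 and 45360001, 238 kb). These interactions went against the fall of read pairs with distance. Reads shared between copies of one sequence were not excluded as their source, as set out under the other observations.

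The second value of each interaction was read as the coverage of its left bin, the bin at the lower position; its meaning is not stated in the list. Its median over the 17287 left bins was 12, with quartiles of 8 and 19. The highest values were 181 on chromosome 6 from 10410001 to 10412000, 173 on chromosome 3 from 171756001 to 171758000 and 162 on chromosome 3 from 128880001 to 128882000. These 3 bins had 4, 7 and 2 partners. With the left bins ranked by coverage and parted into 4 sets of nearly equal size, hubs made up 0.255% of the lowest set (0.127 to 0.455) and 22.5% of the highest (21.3 to 23.8). Across left bins, rho of partners with coverage was 0.41 (0.39 to 0.43). Both values are partly fixed by construction, since the summed read pairs of a left bin never exceeded its coverage and coverage in the lowest set was at most 8. Coverage and distance had a rho of -0.0098, with an interval from -0.029 to 0.012.

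Interactions were unevenly spread over the 23 chromosomes. Relative to the span of each chromosome covered by the list, chromosome 22 had 3.52 times the expected number (95% block interval 1.91 to 5.45), chromosome 17 3.11 times (1.89 to 4.43) and chromosome 19 2.55 times (1.32 to 3.87). These were the 3 chromosomes with an interval wholly above 1, and 4 had one wholly below 1. Chromosome 4 had 0.327 (0.229 to 0.446), chromosome 13 0.330 (0.147 to 0.587), chromosome 18 0.432 (0.205 to 0.685) and chromosome X 0.127 (0.0667 to 0.206). Median left-bin coverage was 10, 8, 8 and 5 on chromosomes 4, 13, 18 and X, against 12 over all left bins. It was 11, 12 and 10 on chromosomes 22, 17 and 19. Fewer contacts and lower coverage were not told apart. The selection of interactions by p63 binding and acetylation is modelled neither by span nor by the gene number used below. The ratios therefore describe the selected list and not the density of contacts in the genome. The chi-square test with 100000 multinomial draws gave p = 1e-05, the smallest these draws can give, and it treats interactions as independent, which they are not. With the number of protein-coding genes as the expectation, no chromosome had an interval wholly above 1, and chromosome 22 had the highest ratio, 1.79 (0.971 to 2.77). The intervals of chromosomes 1, 4 and X lay wholly below 1, at 0.725 (0.507 to 0.970), 0.548 (0.384 to 0.748) and 0.151 (0.0794 to 0.246). Chromosome 19 then stood at 0.713 (0.367 to 1.08), chromosome 17 at 1.48, chromosome 13 at 0.627 and chromosome 18 at 0.848, each with an interval that held 1. With networks counted in place of interactions, against span, the ratios of these chromosomes lay nearer to 1, at 1.76 for chromosome 22, 1.78 for 17, 1.80 for 19, 0.650 for 4, 0.648 for 13 and 0.338 for X, and chromosome 18 had 0.715 (0.424 to 1.05). Chromosomes 15 and 20 then had intervals wholly above 1, at 1.54 (1.19 to 1.88) and 1.58 (1.247 to 1.94), from 1.42 (0.993 to 1.87) and 1.52 (0.837 to 2.35), and chromosome 5 one wholly below 1, at 0.802 (0.618 to 0.989). A network counts once whatever its number of interactions, such as 835 in 1 network of chromosome 17. Ratios nearer to 1 are therefore partly set by construction.

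**Figure D3:**
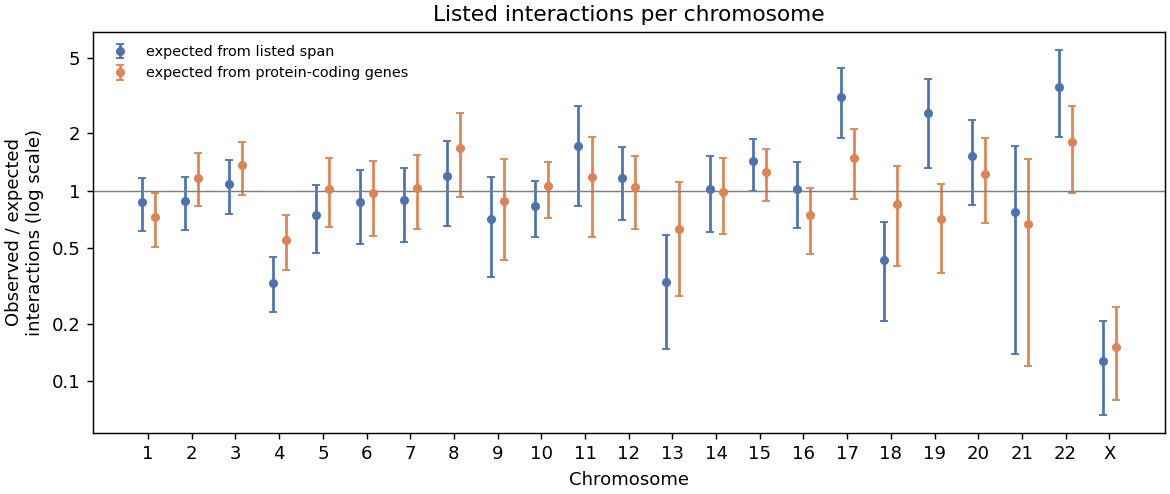
Observed over expected interactions per chromosome on a log scale, with the expectation taken from the listed span of the chromosome (blue) or from its number of protein-coding genes (orange). Bars are 95% intervals from resampled 5 Mb blocks; the intervals of chromosomes 4 and X lie wholly below 1 under both expectations.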

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

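The selections with 2 or more read pairs, the merged count of different bins, the removal of interactions with 5 or more read pairs the settings of the coverage steps and that of the partner sides were chosen after the data were seen. Of 41 values under other settings, 23 stayed within the limit set for them (for a count, 1.5 times; for a chromosome ratio or a correlation, the same side of 1 or 0 by its interval, whatever its size), 5 kept their direction with an interval that now held 1, 12 moved and 1 reversed. Some of the 23 could not change. Counting each unordered pair once left the list as it was, since 0 pairs were listed more than once and 0 had the right bin first. The inner gap between bins is the distance less the bin width of 2 kb. Its median of 88 kb against 90 kb is therefore set by construction. The median distances among the 23 lay inside the main interval of 86 to 94 kb. A count within its limit says nothing of its members.

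Keeping interactions of 2 or more read pairs left 1021 interactions, 1776 different bins, 2 hubs and a median distance of 24 kb. Keeping the better covered part of the list by left-bin coverage left 12845 interactions and 820 hubs, by its construction. Leaving out distances under 20 kb raised the median to 130 kb. A minimum of 10 partners gave 193 hubs, and merging touching bins gave 18088 different regions with 2076 hubs, 11.5% of regions.

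Chromosomes with an interval wholly above 1 numbered 3 against span, 0 against protein-coding genes and 5 with networks counted (15, 17, 19, 20 and 22). Those with an interval wholly below 1 were 4, 13, 18 and X against span, 1, 4 and X against genes, and 4, 5, 13 and X with networks counted. With networks counted, ratios shrank from 3.52 to 1.76 on chromosome 22, from 3.11 to 1.78 on 17, and rose from 0.327 to 0.650 on 4, from 0.330 to 0.648 on 13 and from 0.127 to 0.338 on X. Part of this is set by construction, since a network counts once whatever its number of interactions. Chromosome 19 turned from 2.55 to 0.713 against genes, with an interval that holds 1. Its gene number sets the larger expectation by construction.

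No paired analysis was possible because the list pools both replicates, and for the same reason no run without either replicate was made. With 96.0% of interactions tied at 1 read pair, most single interactions cannot be ranked by read pairs.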

Other observations

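The tests of coverage steps, of interactions with many read pairs, of partner sides and of neighbouring interactions were all chosen after the data were seen, and their results are hypotheses found and tested on the same list. For the steps, the prediction on the density of bins over all chromosomes was written before its result.

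Left-bin coverage changed level along 10 of the 19 chromosomes tested (1, 2, 3, 5, 6, 7, 8, 9, 11 and 14). On chromosome 3 the median rose from 13 before 126796000 to 20 after 127308001, on chromosome 5 from 13 to 21 after 148864001, and on chromosome 11 from 10 to 15 after 47198001. It fell on chromosome 2 from 18 to 12 after 109212001 and on chromosome 14 from 16 to 9 after 55922001. These 5 steps had an adjusted permutation p of 0.00316, from the raw p of 0.000999 that is the smallest 1000 reorderings can give. The step on chromosome 1 was the weakest, with an adjusted permutation p of 0.0494. With 2 Mb pieces reordered 8 steps passed, without those of chromosomes 1 (adjusted p 0.0823) and 6 (0.108). With at least 150 left bins on a side the same 10 chromosomes passed, chromosome 1 at an adjusted p of 0.0456.

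A few strongly covered bins on one side would leave the 25th percentiles of both sides alike. At the 9 steps outside chromosome 1 the ratio of 25th percentiles had an interval without 1. It was 1.56 (1.40 to 1.75) on chromosome 3 and 0.700 (0.636 to 0.875) on chromosome 6. These values argue against that explanation at the 9 steps, where splits were scored on ranks of coverage. However, the ratio was read at the split that parted coverage best, which favours such an interval, so its size may be overstated. Intervals without 1 were also found on chromosomes 10, 12, 17 and 19, whose steps did not pass. On chromosome 1 the lower bound of that ratio was 1, so the explanation stays open there. Density of the list and coverage cannot be told apart: the better covered side was denser at 8 of the 10 steps (two-sided exact sign test p = 0.109), and at 8 of the 9 outside chromosome 1, with a ratio of 1.00 (0.556 to 2.20) on chromosome 14. The prediction written beforehand took 1 sparser chromosome as enough to exclude density, and chromosome 1 was sparser (density ratio 0.452, interval 0.313 to 0.784). That step passed with at least 150 left bins on a side but was lost with 2 Mb pieces. Density is therefore not taken as excluded. A difference in copy number may account for the steps: ratios at the 25th and 75th percentiles had overlapping intervals on 10 of 10 chromosomes, a weak test since the intervals are wide. A broad change of acetylation would give the same values, and no input library was used here, so it stays open. No explanation by a difference between groups was tested, since the design has 1 group.

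The 9 interactions with 5 or more read pairs lay 92 to 494 kb apart and the 12 with 4 lay 10 to 64 kb apart, but the limit of 5 was set after these values were seen, so the exact permutation p of distance (0.000857, adjusted 0.00429 over 5 comparisons) overstates the contrast. Deeper coverage of their left bins was not seen, with a median of 19 against 36.5 in the other set. The exact permutation p between the sets was 0.184 (adjusted 0.230), so the test does not exclude deeper coverage either. The share of left-bin coverage held by the 9 interactions was 38.5% against 11.2% (exact permutation p = 0.0133, adjusted 0.0334). This share decides nothing, since its numerator is the read-pair count by which the sets were chosen. Reads shared between copies of one sequence, or a difference of these cells from the reference assembly, could give contacts with few other partners. The bins of the 9 had a median of 1 other partner against 8, with an exact permutation p of 0.0321 (adjusted 0.0535). Of the 9, 0 were without any other partner, against 1 of the 12. Only the choice of the adjusted value, made after both were seen, leaves this explanation open. Frequent looping also stays open: 4 of the 9 had another interaction within 1 bin at both ends, against 7 of the 12 (Fisher's exact p = 0.670). This comparison is not matched for distance. Over the whole list such neighbours were found for 42.3% of interactions at 10 to 20 kb. The share was 14.1% at 100 to 200 kb and 7.60% at 200 to 500 kb. The test therefore cannot show that the sets are alike.

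Of 193 bins with at least 10 partners, 18 had uneven sides when equal sides were expected. With the layout of listed bins as the expectation, 0 remained by the adjusted binomial test, but a bin's own partners are part of that layout. With the bins listed through it alone left out, which favours unevenness, 5 remained, so an uneven layout and looping to one side both stay open. Of the 193 bins, 14 had an unadjusted p under 0.05 with the full layout and 18 without those bins, where the exact tests give 6.24 and 6.26 by chance if partners were independent. The strongest with the full layout was on chromosome 2 from 28616001 to 28618000, with 18 of 18 partners at lower positions and an adjusted p of 0.0555. None of 358 merged stretches was uneven after adjustment with the full layout.

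Another interaction lay within 1 bin at both ends for 20.8% of the list, against a mean of 20.4% and at most 20.7% in 100 shuffled lists. Within 2 bins the share was 30.236%, against at most 30.15%, and from 1000 to 2000 kb it was 1.42% against at most 1.34%. These were the 3 of 20 comparisons, over distance classes and both tolerances, in which the list lay above every shuffled list. The shuffles moved the right bin of only 32.5% of interactions, and 9.43% at 10 to 20 kb, so the shuffled lists resemble the list itself and the size of the differences cannot be read from them.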
